A study of Mus musculus with 53 samples.

How the data were processed

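Total RNA of 53 samples of mouse T-cell lymphoblast tumours had been extracted with Trizol, labelled as biotin cRNA and hybridized to oligonucleotide arrays, per the labels. The authors deposited normalized signal intensity values on a linear scale for 22690 probe sets per array. The normalization method is not given in the sources used here, and it can change any difference in overall level between groups. The intensities were converted to log2 here, and all 53 value columns were used. The number of arrays limits the precision.

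Groups are the genetic backgrounds named in the labels, with replicate numbers from the titles. No source says that the samples of a background come from separate animals, so p-values measure only the spread between these samples, which may be technical. No pair of arrays held identical values (highest Pearson correlation 0.983). Probe sets were named through the gene table given with the data: 20393 carried 1 gene symbol, 691 several and 1606 none used here, and 64 were controls. Of the probe sets, 20364 were matched by Entrez identifier. Where a gene had several probe sets (4958 of 12394 genes), the one of highest mean over all arrays was used. Genes above the array median on at least 3 arrays were kept, which left 9157. Genes outside these entered only the alternative without a filter and, for Hoxd13, Olig1, Olig2, Tal1 and Tlx1, the tests of targeted genes.

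Differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05; counts of genes that also differed by 2-fold are given beside. TLX1 tumours and crossed tumours were each compared with the 41 tumours of 13 other backgrounds and with each other. Each background was also compared with the mean of the means of the other backgrounds in a model of all 53 arrays. Gene lists were fixed before the data were examined, as were the groups, the tests, the alternatives listed first and the rule for named genes. The 21 lists with a test were examined with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Targeted genes formed a family of 21 tests. Quality measures were compared with exact permutation tests in groups of 6 and with 100000 permutations otherwise, and the similarity of arrays with 100000 reassignments of the background labels. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used for these and for the plots.

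Named genes followed a rule. Among genes past the threshold, the 10 highest and 10 lowest differences were taken for TLX1 tumours against the other backgrounds and for crossed against TLX1 tumours, and the 5 highest and 5 lowest for crossed tumours against the other backgrounds. Each had to lie outside the interquartile range of the comparison samples in every sample of the TLX1 or crossed group, or, between those groups, to have all 6 crossed tumours on the same side of the TLX1 median. Symbols of unnamed transcripts, probe sets of several genes, rearranging receptor segments and sex-linked genes were left out. Lists were illustrated with up to 4 called members of largest difference, and each other background with up to 3 high and 2 low genes.

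Array sets were found by clustering the arrays on the 27 bacterial control probe sets, after the values were seen. Their number, 4, was chosen and other numbers were not tried here. Alternatives were no filter and a stricter filter (5692 genes), the mean of all probe sets or the probe set of largest interquartile range, quantile normalization, centring of each array on its median, trended and robust eBayes, leaving out each replicate or background, a replicate block, other groupings of the controls, and background as a random block. Leaving out a replicate of a background with 2 leaves a lone sample, which limma then assumes to vary like the other groups. Chosen after seeing the data were array set as a block, the p53 knockout arrays of the TLX1 array set as the only controls, the largest array set alone, the beta-actin ratio as a covariate, and the removal of p53 knockout replicate 2 or of the 2 arrays of highest beta-actin ratio. Array set as a block gives the same TLX1 difference as those p53 knockout arrays alone, with the spread taken over more arrays. The pipeline was tested on simulated data with 200 changed genes among 9157. A log2 change of 1 was recovered for 92.5% of changed genes in the design of 6 against 41 TLX1 and control arrays, for 86.6% in 6 against 6 and for 43.3% in 6 against 2. The last used the spread pooled within all 15 backgrounds, the others that of their own arrays.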

Results

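RNA levels were measured in 53 samples of T-cell lymphoblast tumours from mice of 15 lymphoma-prone genetic backgrounds. Each sample had 1 oligonucleotide array of 22690 probe sets. The samples are called tumours here, although no source says that those of a background come from separate animals. The labels give every tumour a TLX1 status, so the design sets tumours driven by TLX1, a homeobox transcription factor, beside other T-cell lymphomas. TLX1 transgenic mice gave 6 tumours. TLX1 transgenic mice that were also heterozygous for a RUNX gene (RUNX1 in the sample titles) gave another 6, here called crossed tumours; their status label says TLX1 negative although their genotype names the transgene. The other 13 backgrounds gave 41 tumours. Cdkn2a knockout mice with retroviral insertional mutagenesis gave 9. There were 3 each from beta-catenin, LMO1, LMO1 with Olig, NUP98-HOXD13, Tal1 with LMO2 and ThPOK transgenic mice, from mice labelled Ikaros plastic and from p53 knockout mice. E2A knockout, Rag with E2A knockout, Pokemon transgenic and Tal1 transgenic mice gave 2 each. Normal thymus was not analysed here. The median intensity of an array ranged from 377 to 590 (mean 483 over 53 arrays), and the number of arrays limits the precision.

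Probe sets that carry no mouse gene divided the arrays along the groups. Clustering on the 27 probe sets for bacterial control transcripts, cut at a chosen number of 4, gave 4 array sets. The 6 TLX1 arrays shared a set of 8 with p53 knockout replicates 1 and 2, the 6 crossed arrays formed a set of their own, 38 arrays of the other backgrounds formed the largest set, and Tal1 with LMO2 replicate 2 stood alone. The log2 ratio of 3' to 5' beta-actin signal, which grows with RNA degradation, was 1.39 ± 0.62 (SD, n = 6) in TLX1 tumours, 0.77 ± 0.11 (n = 6) in crossed tumours and 0.31 ± 0.31 (n = 41) in the others. TLX1 tumours exceeded the others in this ratio (permutation p = 4e-05, adjusted 0.00012 over 15 tests) and exceeded crossed tumours (exact permutation p = 0.0195, adjusted 0.0244), both tests two-sided. An 18S ribosomal RNA control probe set, that of the 3' end, read 12.71 ± 0.31 (log2, SD, n = 6) in crossed tumours against 9.15 ± 0.17 in TLX1 tumours (exact permutation p = 0.00216, adjusted 0.00361) and 8.84 ± 0.51 (n = 41) in the others. The log2 array median was 8.61 ± 0.03 in crossed tumours, 8.99 ± 0.06 in TLX1 tumours and 8.94 ± 0.11 in the others.

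The genes that the backgrounds target were examined first, as a check of the labels. Lmo1, which encodes a LIM-domain partner of TAL1, was 4.46 ± 0.22 (log2 difference, SE) above the mean of the other backgrounds in LMO1 tumours (12.91 ± 0.41, SD, n = 3) and 4.51 ± 0.22 above it in LMO1 with Olig tumours (12.95 ± 0.55, n = 3). Zbtb7a, the gene of the Pokemon repressor, rose by 3.33 ± 0.20 in Pokemon tumours (12.07 ± 0.07, n = 2). Tcf3, which encodes the E2A transcription factors, fell in E2A knockout tumours (-0.85 ± 0.21, adjusted p = 0.000653) and in Rag with E2A knockout tumours (-0.72 ± 0.21, adjusted p = 0.00367), and its other probe sets lay from -1.86 to -1.39. These calls were lost without E2A knockout replicate 1 (-0.59, adjusted p = 0.0926) and without Rag with E2A knockout replicate 4 (-0.60, adjusted p = 0.0944). Runx1 fell in crossed tumours (-1.16 ± 0.11, adjusted p = 1.77e-12) with its 5 probe sets between -1.16 and -0.20. This is a weak check, since 3783 of 9157 genes were lower in crossed tumours in this kind of contrast. Against TLX1 tumours its probe sets also split, with 1 at 9.41 in crossed and 8.93 in TLX1 tumours and another at 8.96 and 8.115. Ikzf1, which encodes Ikaros, was above the mean of the other backgrounds in Ikaros plastic tumours (0.92 ± 0.21, adjusted p = 0.000349; 11.22 ± 0.42, n = 3). It was not particular to them, since beta-catenin tumours read 11.30 to 11.50. The crossed arrays, at 8.07 to 8.53, are part of the mean compared. Ctnnb1, the beta-catenin gene, rose by 0.33 ± 0.12 in beta-catenin tumours (adjusted p = 0.018; 0.999 and 0.71 by its other probe sets), a call lost without replicate 3 (0.20, adjusted p = 0.254). Nup98 rose by 0.30 ± 0.11 in NUP98-HOXD13 tumours (adjusted p = 0.018; 0.24 and 0.151 without replicate 3). In all, 11 of 21 pairs of gene and background passed the test in limma, among them Lmo2 in Tal1 with LMO2 tumours and Tlx1 in crossed tumours, which were lower where the label names a transgene.

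Several transgenes were not seen by the mouse probe sets. Tlx1 differed by 0.05 ± 0.07 in TLX1 tumours (7.79 ± 0.17, n = 6; adjusted p = 0.627) and by -0.32 ± 0.07 in crossed tumours (7.45 ± 0.06, n = 6; adjusted p = 0.000453), which became -0.07 (adjusted p = 0.339) with quantile normalization. Lmo2 was below the other backgrounds in Tal1 with LMO2 tumours (-0.95 ± 0.35, adjusted p = 0.018), a call lost without replicate 2 or replicate 3 (adjusted p = 0.0729 and 0.0557). Tal1 differed by -0.08 ± 0.14 in Tal1 tumours and -0.16 ± 0.12 in Tal1 with LMO2 tumours. Olig1 differed by -0.09 ± 0.06 and Olig2 by 0.10 ± 0.07 in LMO1 with Olig tumours, whose title and genotype label name different Olig genes. Hoxd13 (-0.06 ± 0.13; 0.00 with quantile normalization), Cdkn2a (-0.01 ± 0.14), Rag1 (0.61 ± 0.82), Rag2 (0.09 ± 0.30) and Zbtb7b, the ThPOK gene (0.27 ± 0.19; 0.88 by its other probe set), did not pass in their backgrounds. A probe set outside a deleted part, or a transgene from another species, need not show in these values. Trp53 was not analysed here.

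**Figure D1:**
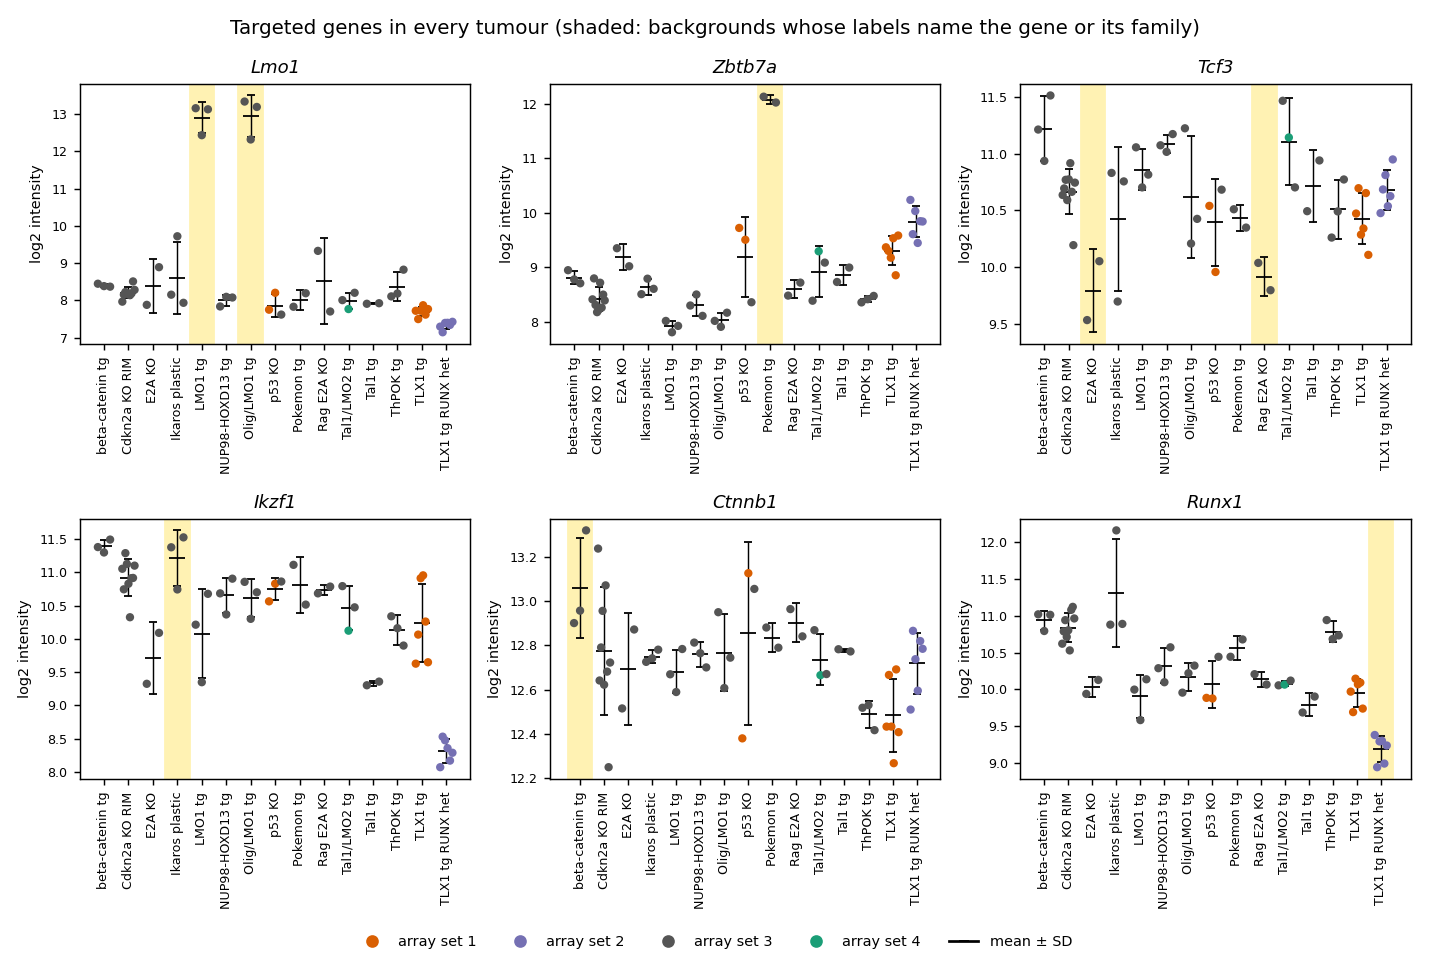
Log2 intensity of 6 targeted genes on each of the 53 arrays, by background, with points coloured by array set, bars for the mean ± SD and shading for backgrounds whose labels name the gene or its family. Lmo1 stood near 12.9 in both LMO1 backgrounds and Zbtb7a at 12.07 in Pokemon tumours.

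The genes that stood highest in TLX1 tumours against the 41 tumours of the other backgrounds are given first. Dlx1, a homeobox transcription factor gene, was 2.35 ± 0.38 higher (log2 difference, SE; 10.10 ± 0.42, SD, n = 6, against 7.74 ± 0.94, n = 41; adjusted p = 5.49e-06). Dok5, an adaptor of receptor tyrosine kinase signalling, was 2.85 ± 0.31 higher (7.19-fold; adjusted p = 1.76e-09). The transcription factor genes Klf15 and Hoxa13 were 2.66 ± 0.28 and 2.34 ± 0.24 higher, and Dll4, which encodes a Notch ligand, was 2.32 ± 0.26 higher (0.29 by its other probe set). The list of HOX genes and cofactors did not pass (1 of 6 rose and 1 fell; camera adjusted p = 0.763). On the low side stood H2-T3, a nonclassical class I histocompatibility gene (-2.48 ± 0.79, adjusted p = 0.0135), Gsdme, which encodes a pore-forming gasdermin (-2.36 ± 0.31, adjusted p = 1.41e-07; -0.26 by its other probe set), and Cldn10, a claudin of tight junctions (-2.17 ± 0.37).

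Set beside the p53 knockout arrays of their own array set, most of these differences were absent. Dok5 read 10.82 and 10.63 on p53 knockout replicates 1 and 2, so that the TLX1 difference within the set was -0.03. Replicate 3, which lies in the largest set, read 9.59, above the mean of 7.85 ± 0.77 (SD, n = 41) over the other backgrounds. The within-set differences were 0.16 for Klf15, 0.12 for Hoxa13, -0.25 for Dll4, 0.10 for H2-T3 and -0.46 for Gsdme. Dlx1 read 7.56, 7.28 and 7.29 on the 3 p53 knockout arrays. Its within-set difference was 2.68 (limma adjusted p = 0.0508, or 0.0429 with array set as a block). With p53 knockout replicate 2 also left out, which leaves a lone control array in the set, it was 2.54 ± 0.96. Smim3, a small membrane protein gene, was 1.72 ± 0.22 higher over all arrays. Within the set it was 1.73 higher (limma adjusted p = 0.396, or 0.0225 with array set as a block), and 1.63 ± 0.55 higher with p53 knockout replicate 2 also left out. Sh3gl3, an endophilin gene, was -1.30 ± 0.43 over all arrays and -1.93 within the set (adjusted p = 0.0508; 0.205 with array set as a block).

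Across 9157 genes, 1725 were higher and 1211 lower in TLX1 tumours at an adjusted p under 0.05, of which 330 and 54 differed by 2-fold or more. Other genes at the high end were Prss22 (2.65), Caln1 (2.58), Serpinf1 (2.39), Mat1a (2.38) and Fmo2 (2.27), and others at the low end were Smim10l1 (-1.81), Ctse (-1.67), Sp3 (-1.498), Sephs2 (-1.40), Zfp991 (-1.38) and Moxd2 (-1.27). Other probe sets of these genes gave 0.73 for Serpinf1, -0.005 for Smim10l1, -0.255 for Ctse, up to -0.38 for Sephs2 and, with the opposite sign, -0.068 for Fmo2 and 0.599 for Zfp991. Within the array set the direction turned for Prss22 (-0.92), Caln1 (-0.47), Serpinf1 (-0.62), Mat1a (-0.59), Fmo2 (-0.41), Ctse (1.32), Sp3 (0.33), Sephs2 (0.14) and Moxd2 (0.46). The Ctse call was lost without TLX1 replicate 5 (-1.37, adjusted p = 0.0779). Against the 2 p53 knockout arrays of the same set, limma called 0 genes (891 at an unadjusted p under 0.05), and 1236 of the 2936 called genes had the same sign there. With array set as a block 58 were higher and 78 lower, of which 14 were among the 2936 with the same sign, with the beta-actin ratio as a covariate 81 and 22 were called, and with background as a random block 190 and 17.

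**Figure D2:**
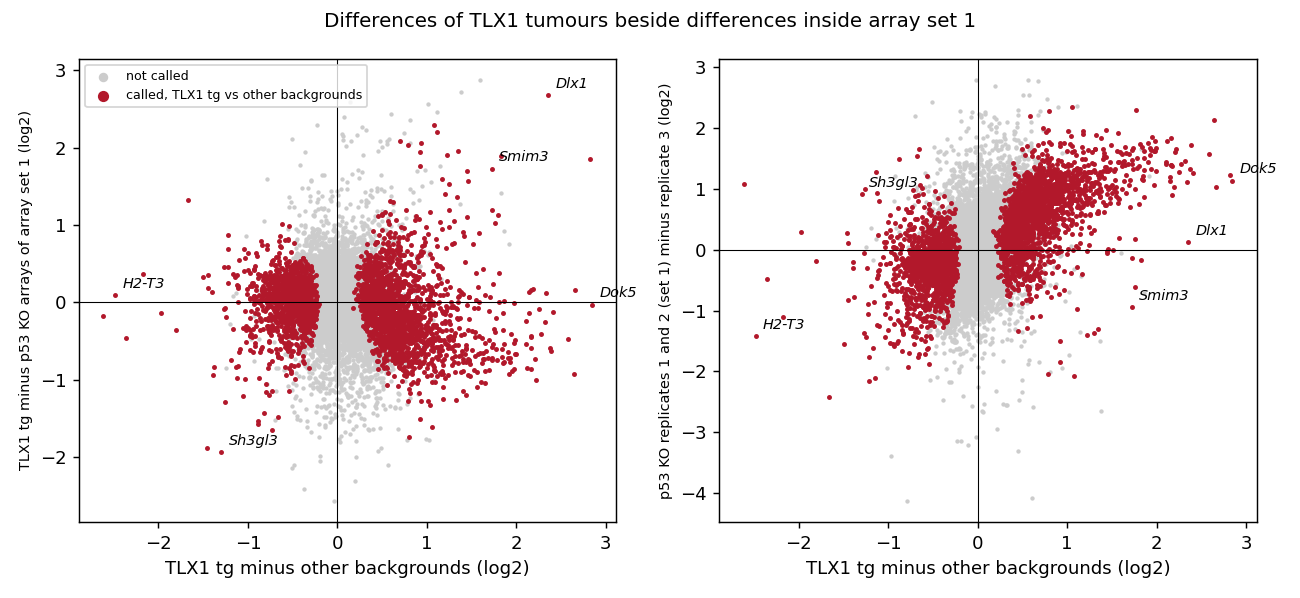
Log2 differences of genes between TLX1 tumours and the other backgrounds (x axis) against the difference from p53 knockout arrays of the same array set and against the difference between p53 knockout arrays of the different array sets (y axes). The second of these correlated with the TLX1 difference at r = 0.68 across 3651 called genes, which are not independent replicates.

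Among the gene lists, that of early T-cell progenitors was higher in TLX1 tumours (camera adjusted p = 0.0373; adjusted p = 0.877 with an estimated correlation). Of its 10 measured members 5 rose, also 5 adjusted over the list alone. They included the receptor tyrosine kinase genes Flt3 (1.65 ± 0.26) and Kit (1.04 ± 0.23; 0.16 by its other probe set) and the transcription factor genes Lyl1 (1.63 ± 0.23) and Bcl11a (0.83 ± 0.16). Within the array set the differences were -0.52 for Flt3, -0.77 for Kit, 0.43 for Lyl1 and 0.15 for Bcl11a. With p53 knockout replicate 2 also left out they were -0.49 for Flt3, -0.71 for Kit and 1.13 for Lyl1. DNA replication genes were lower as a list (adjusted p = 0.0305; 0.877 with an estimated correlation), with 3 of 22 fallen, also 3 adjusted over the list alone, among them the clamp loader gene Rfc3 (-1.15 ± 0.24; 0.33 within the set). Against the p53 knockout arrays of the same set the DNA replication list turned to higher (adjusted p = 4.85e-05), where replicate 2 is itself low in these genes (median -1.36 against the other p53 knockout arrays). The list of Myc targets and ribosome biogenesis was lower too (adjusted p = 0.0305; 0.877 with an estimated correlation), with 4 of 17 fallen and 3 adjusted over the list alone, among them the helicase gene Eif4a1 (-0.95 ± 0.18; 0.25 within the set).

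Single markers of other cells were higher in TLX1 tumours, in lists that did not pass (camera adjusted p = 0.605 for myeloid, 0.281 for stromal, endothelial and epithelial and 0.743 for erythroid genes). Over all genes 1725 of 9157 were called higher, a share near that in these lists. Of 18 myeloid genes 3 rose, among them Csf1r, the macrophage growth factor receptor (1.05 ± 0.24; its other probe sets down to -0.18; -0.52 within the set), and of 13 stromal, endothelial and epithelial genes 2 rose. Hba-a1, a haemoglobin gene, rose by 1.16 ± 0.28 (-0.92 within the set) and was the member of 5 erythroid genes that passed. Of 12 mature T-cell genes 4 rose (camera adjusted p = 0.147), among them the survival gene Bcl2 (1.11 ± 0.18; 0.73 within the set). Myc fell (-1.23 ± 0.26, adjusted p = 0.000375; 0.25 within the set).

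Crossed tumours were set against TLX1 tumours to ask what differs with RUNX heterozygosity. Several genes of the double-positive thymocyte stage fell, although the list did not pass (camera adjusted p = 0.48). Rag2, which encodes a subunit of the V(D)J recombinase, was 7.01 ± 0.17 (SD, n = 6) in crossed and 10.37 ± 0.30 (n = 6) in TLX1 tumours, a difference of -3.36 ± 0.14 (SE; adjusted p = 1.31e-09). Rag1, which encodes its partner, fell by 2.25 ± 0.57 and Ptcra, the pre-T-cell receptor alpha gene, by 2.73 ± 0.43. Within the TLX1 array set Rag2 did not go with Rag1. It read 10.16 and 10.69 on TLX1 replicates 1 and 6 and 10.65 on p53 knockout replicate 2. Rag1 read 9.25, 9.502 and 7.47 there, below the 11.31 or more of TLX1 replicates 2 to 5. The fall of Rag2 is therefore a weak sign of thymocyte stage. The coreceptor genes Cd8a (-2.04 ± 0.40), Cd4 (-1.84 ± 0.22) and Cd8b1 (-1.63 ± 0.41) were also lower. Of the 14 double-positive stage genes 7 fell and 1 rose, with the same counts adjusted over the list alone, or 6 and 3 with each array centred on its median. The gene that rose, the chemokine receptor gene Ccr9 (1.64 ± 0.62, adjusted p = 0.039), lost its call without most single arrays, with adjusted p up to 0.083.

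Some Notch target genes were lower in crossed tumours, in a list that did not pass (camera adjusted p = 0.38). Dtx1, which encodes a Notch-regulated ubiquitin ligase, was 7.63 ± 0.07 in crossed and 11.02 ± 1.54 in TLX1 tumours (-3.38 ± 0.56, adjusted p = 0.000192). The receptor genes Notch1 (-1.95 ± 0.55) and Notch3 (-1.95 ± 0.46) fell, and 7 of 13 members fell in all (7 adjusted over the list alone), or 4 with 2 risen when arrays were centred and 4 with 1 risen after quantile normalization. Of 7 genes induced by T-cell receptor signalling 5 fell (camera adjusted p = 0.209; 5 adjusted over the list alone), led by the nuclear receptor gene Nr4a3 (-4.23 ± 0.13) and the transcription factor genes Egr3 (-1.49 ± 0.18) and Egr1 (-1.25 ± 0.27). Of 17 T-lineage identity genes 9 fell (camera adjusted p = 0.537; 9 adjusted over the list alone), among them the kinase gene Fyn (-1.57 ± 0.17) and the surface receptor gene Cd6 (-1.39 ± 0.20). With each array centred, 5 T-lineage genes rose and 4 fell.

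Mitosis and checkpoint genes were higher in crossed tumours as a list (camera adjusted p = 0.0377), a call lost with an estimated correlation (adjusted p = 0.792) and with the mean of probe sets (0.175). The fry test, which does not compare with other genes, gave an adjusted p of 0.343 for a shift in 1 direction. For changes in either direction fry gave 4.07e-09. Of 22 members 11 rose and 2 fell, or 12 and 2 adjusted over the list alone, 17 and 2 with arrays centred and 9 and 2 with quantile normalization. The kinesin genes Cenpe (1.07 ± 0.25) and Kif11 (0.84 ± 0.26; 0.32 by another probe set) and the kinase gene Aurkb (0.66 ± 0.20) rose, and the checkpoint gene Mad1l1 fell (-1.502 ± 0.09). Among early progenitor genes Flt3 fell by 2.84 ± 0.26, while Kit was -2.09 by the probe set used and 1.74 by its other probe set. Lyl1 differed by 0.86 ± 0.42 (adjusted p = 0.102; 1.12 and 0.0283 without TLX1 replicate 4).

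Single markers of other cells differed, in lists that did not pass (camera adjusted p = 0.413 for erythroid, 0.537 for B-cell and 0.413 for myeloid genes). Over all 9157 genes 1637 were higher and 3322 lower. Hba-a1 fell by 3.11 ± 0.31 with 3 of 5 erythroid genes, and the B-cell receptor genes Cd22 (-2.04 ± 0.22) and Cd79a (-1.65 ± 0.20) fell with 4 of 10 B-cell genes, a list whose median was -0.22 and turned to 0.16 with arrays centred. Of the 18 myeloid genes 2 rose and 2 fell (6 and 1 with arrays centred), with the integrin gene Itgam at 1.39 ± 0.32 and Csf1r at -1.46 ± 0.16. Id2, an inhibitor of E proteins on the innate lymphoid list, rose by 1.69 ± 0.31. Runx1 itself was -0.76 ± 0.11 by the probe set used (adjusted p = 8.26e-05), with 5 probe sets between -1.19 and 0.85.

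The differences that led each end of this comparison often belonged to a single probe set. Prss22 (-5.77 ± 0.23) and Slco6c1 (-4.64 ± 0.19) have 1 probe set each. Kalrn, a guanine nucleotide exchange factor gene, ranged over its 3 probe sets from -5.29 to -0.15, and Btrc, an F-box protein gene, over 2 from -5.16 to -0.13. Lig3 ranged from -4.82 to 0.64, Krtap19-1 from -4.73 to 0.71, Lor from -4.46 to -0.41, Samhd1 from -4.46 to 0.72, Steap1 from -4.38 to -0.05 and Tspan33 from -4.25 to -0.46. At the high end, the transcription factor genes Sp3 and Fli1 were 2.56 ± 0.24 and 1.998 ± 0.13, with Fli1 at -0.05 by its other probe set. Chst15, a sulfotransferase gene, was 1.88 ± 0.40 and 1.33 by its probe sets, and Snrpd3 ranged from -0.85 to 1.80. H2-Q2 (2.14), Trat1 (2.02), Tob1 (2.01), Usp25 (1.93), Ankrd49 (1.92) and Zcchc10 (1.83) complete the named genes; the H2-Q2 call (adjusted p = 0.039) was lost without most single arrays, with adjusted p up to 0.0877.

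In total 1637 genes were higher and 3322 lower in crossed than in TLX1 tumours, 194 and 1438 of them by 2-fold or more, and the median over all genes was -0.12. Quantile normalization gave 2281 higher and 2474 lower (median 0.03), and centring each array gave 3860 and 2050 (median 0.25). These groups lay in different array sets, so array set and cross cannot be told apart, and 21 of the 27 bacterial control probe sets also passed the test between them.

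**Figure D3:**
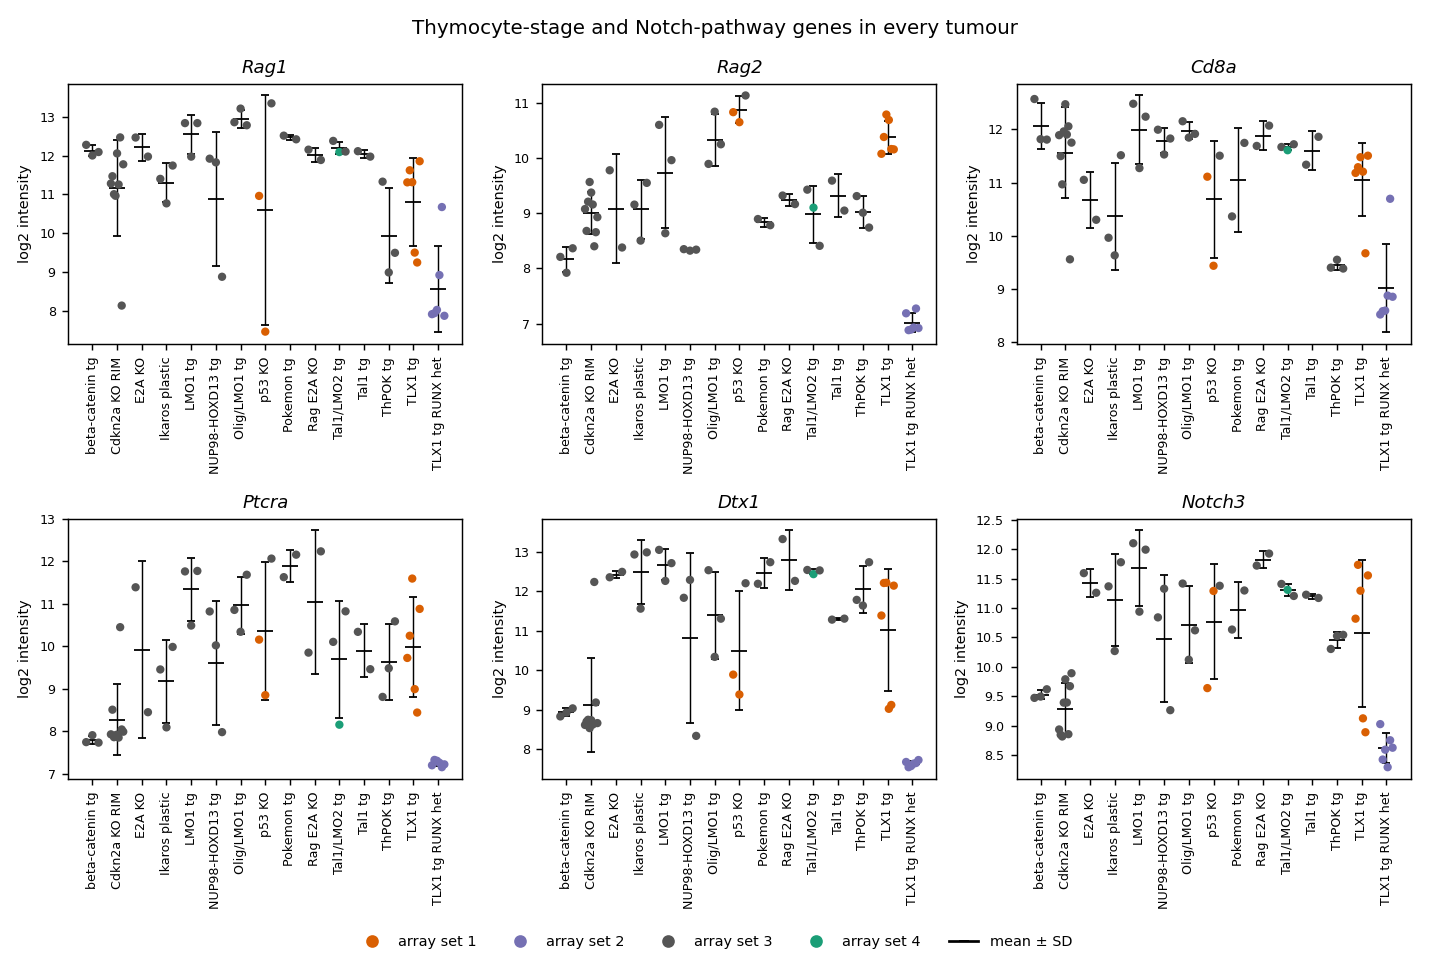
Log2 intensity of Rag1, Rag2, Cd8a, Ptcra, Dtx1 and Notch3 on each of the 53 arrays, by background, with bars for the mean ± SD. Rag2 averaged 7.01 in crossed tumours and 10.37 in TLX1 tumours.

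Against the same 41 tumours of other backgrounds, several Notch target and double-positive stage genes were again low in crossed tumours, in lists that did not pass. Dtx1 fell by 3.44 ± 0.68 (7.63 ± 0.07, SD, n = 6, against 11.07 ± 1.71, n = 41; adjusted p = 2.77e-05). Of the 13 Notch target genes 10 fell, or 11 adjusted over the list alone (camera adjusted p = 0.193), among them Notch3 (-1.93 ± 0.40) and the pseudokinase gene Trib2 (-2.10 ± 0.42). With quantile normalization or arrays centred 5 of them fell. Rag1 (-3.04 ± 0.54), Cd8b1 (-2.85 ± 0.46), Cd8a (-2.31 ± 0.39) and Cd4 (-1.59 ± 0.35) were among 7 of 14 double-positive stage genes that fell, under each scaling and adjusted over the list alone, with 1 that rose (camera adjusted p = 0.431). Of 17 T-lineage genes 7 fell (camera adjusted p = 0.673; 7 adjusted over the list alone; 3 rose and 6 fell with arrays centred), led by the adhesion receptor gene Cd2 (-2.31 ± 0.38) and the Wnt effector gene Lef1 (-2.26 ± 0.41). That is near the share over all genes, where 3412 of 9157 fell. Il7r, the interleukin 7 receptor gene, rose by 1.72 ± 0.45.

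The highest differences were Dppa2 (2.79 ± 0.18), Dlx1 (2.65 ± 0.40), Lyl1 (2.48 ± 0.21), Chst15 (2.38 ± 0.36) and the transglutaminase subunit gene F13a1 (2.24 ± 0.37). At the low end, Btrc (-4.94 ± 0.20), Lor (-3.77 ± 0.27), Kalrn (-3.74 ± 0.30) and Cbarp (-3.43 ± 0.24) each had another probe set at -0.40 or nearer 0. Of the myeloid genes 4 of 18 rose (3 adjusted over the list alone, 7 with arrays centred and 5 with quantile normalization). Of the stromal, endothelial and epithelial genes 3 of 13 rose and 2 fell, against 7 and 0 with arrays centred and 4 and 0 with quantile normalization. In all 1702 genes were higher and 3412 lower, 220 and 980 by 2-fold or more, against 2003 and 2593 with quantile normalization and 3623 and 2146 with arrays centred. Camera called 0 of the 21 lists (fry called 11), with unadjusted p under 0.05 for the Notch target (0.0368), T-cell receptor induced (0.0266), Wnt target (0.0331) and myeloid (0.0304) lists.

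Some genes differed on average from the other backgrounds in both TLX1 groups, with overlapping single arrays (Dlx1 reached 10.28 and Smim3 10.17 on arrays of other backgrounds). Dlx1 was 2.35 and 2.65 higher in TLX1 and crossed tumours, Smim3 1.72 and 1.88, Lyl1 1.63 and 2.48, the poly(ADP-ribose) polymerase gene Parp3 1.81 and 2.08, and Emid1 1.73 and 1.58. H2-T3 was at -2.48 and -2.39, Gsdme at -2.36 and -2.01 and Sephs2 at -1.40 and -1.97. Within the TLX1 array set, against the p53 knockout arrays, Lyl1 differed by 0.43, Parp3 by 0.39, Emid1 by 1.19, H2-T3 by 0.10, Gsdme by -0.46 and Sephs2 by 0.14. Against p53 knockout replicate 1 alone, without replicate 2, which is low in T-cell transcripts, Lyl1 differed by 1.13, Parp3 by 1.11 and Emid1 by 1.03. H2-T3 differed by -0.06, Gsdme by -0.35 and Sephs2 by -0.11 there. At 2-fold or more 30 genes were higher in both and 15 lower in both. Of these 45 genes, 31 had the same sign within the TLX1 array set. Without the 2-fold limit 350 were higher in both and 550 lower in both, while 852 were higher in TLX1 and lower in crossed tumours and 141 the reverse. Over all 9157 genes the log2 differences of the groups correlated at r = -0.04 (Spearman's rho = 0.02), where unchanged groups against the same 41 arrays gave 0.13 on average. The covariance was -0.0125 against 0.0051 simulated, and with the controls split by background r was 0.09 and -0.23. Genes are not independent replicates in these correlations.

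**Figure D4:**
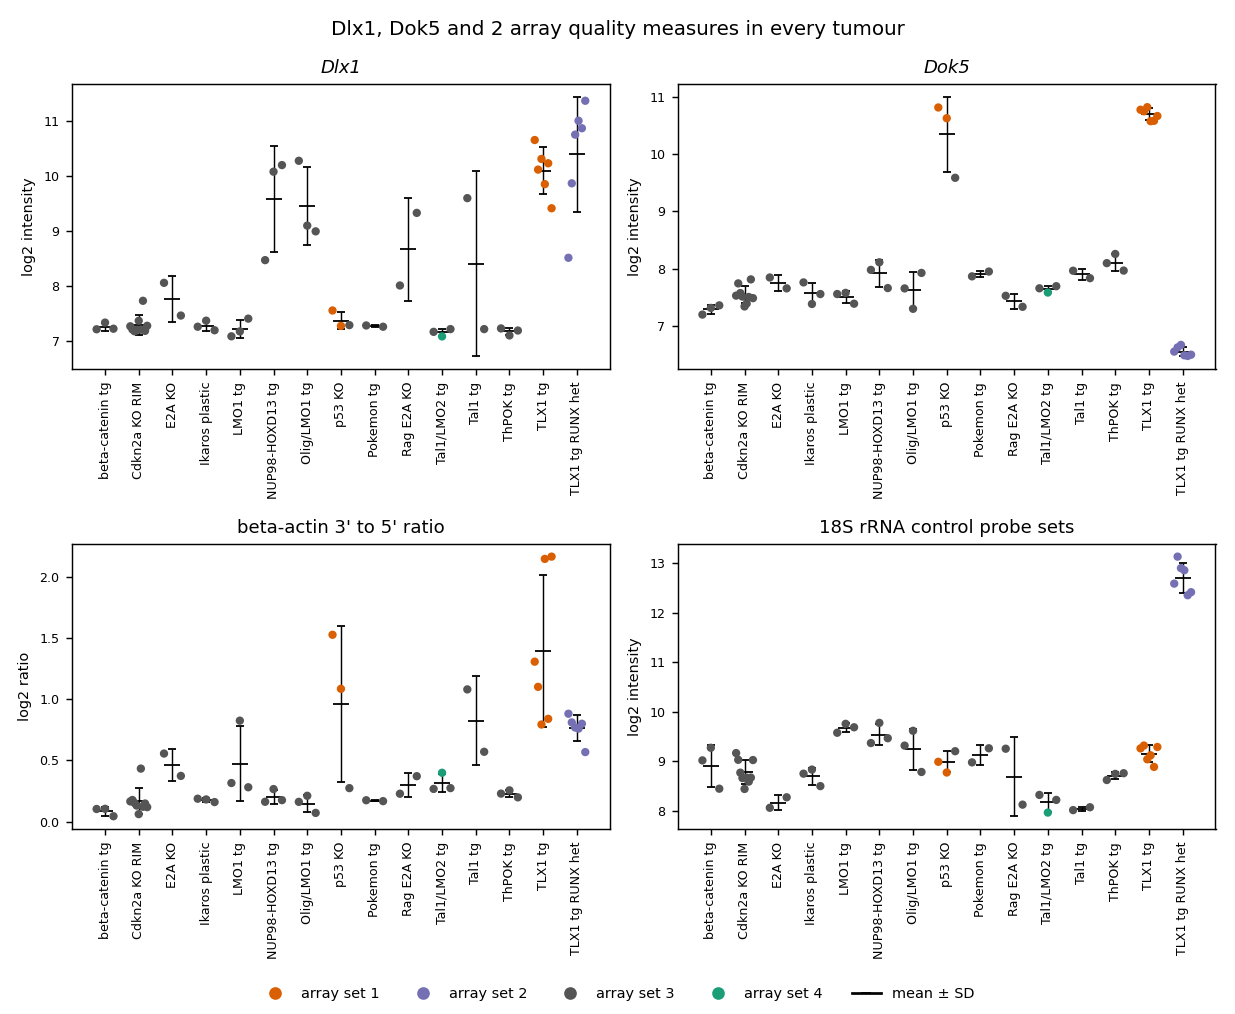
Log2 intensity of Dlx1 and Dok5, the log2 3' to 5' ratio of beta-actin and the log2 18S ribosomal RNA signal on each of the 53 arrays, by background, coloured by array set, with bars for the mean ± SD. Dok5 read 10.82 and 10.63 on p53 knockout replicates 1 and 2, beside a mean of 10.70 in TLX1 tumours, while Dlx1 read 7.56 and 7.28 there.

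Each background was also set against the mean of all others. Beta-catenin tumours had high Wnt pathway genes. Wif1, which encodes a secreted Wnt inhibitor, was 4.70 ± 0.60 higher (11.67 ± 0.43, SD, n = 3; 4.66 within the 38-array set), and Apcdd1, another Wnt antagonist gene, was 4.27 ± 0.73 higher. Of 8 Wnt target genes 6 rose, among them Axin2 (1.81 ± 0.26) and Nkd1 (1.26 ± 0.15), and the list passed (adjusted p = 0.000943; adjusted p = 0.127 with an estimated correlation). Notch1 fell by 3.78 ± 0.53, and 9 of 13 Notch target genes fell with 2 risen (adjusted p = 0.0238; 0.952 with an estimated correlation). Beside them 9 of 10 B-cell genes rose, among them Ms4a1 (1.56 ± 0.34) and Cd74 (1.70 ± 0.38) (adjusted p = 0.00811; 0.952 with an estimated correlation). Sh3bgrl2 rose by 3.84 ± 0.49 and Arpp21 fell by 3.47 ± 0.61.

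Cdkn2a knockout tumours with retroviral insertions had low Notch target genes as well. Notch1 fell by 2.80 ± 0.33, Dtx1 by 2.24 ± 0.38 and Ptcra by 1.62 ± 0.36, while Myc rose by 1.05 ± 0.15. Of the 13 Notch targets 10 fell and 3 rose (adjusted p = 0.0084; 0.952 with an estimated correlation). Ctse, which encodes the protease cathepsin E, rose by 2.65 ± 0.29 (13.92 ± 0.19, n = 9; 2.31 within the 38-array set), Smim27 by 1.86 ± 0.11 and Sh3bgrl2 by 1.79 ± 0.30. Mndal, an interferon-inducible gene, fell by 2.52 ± 0.32 and Aldh1b1 by 2.37 ± 0.32. Mndal was also low in Rag with E2A knockout (-2.80) and Tal1 with LMO2 tumours (-2.94).

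Ikaros plastic tumours had high Mucl2 (5.40 ± 0.73), Scgb2b27 (4.39 ± 0.67) and Crisp3 (3.82 ± 0.49), whose SDs over the 3 tumours were 1.77, 2.62 and 2.76. Ddc (-2.25) and Tubb2b (-2.14) were low, and the Ddc call was lost without replicate 2 (adjusted p = 0.0633). Of 22 mitosis and checkpoint genes 8 fell, among them the kinase genes Aurka (-0.85 ± 0.26) and Ttk (-0.73 ± 0.17) (adjusted p = 7.71e-05; 0.952 with an estimated correlation). ThPOK tumours had high Smim27 (2.38 ± 0.18), the gluconeogenic enzyme gene Fbp1 (2.28 ± 0.55) and Popdc3 (2.26 ± 0.43), with Erdr1 at -2.84 ± 0.46 and Jchain at -2.52 ± 0.63.

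LMO1 tumours had high Fgf13 (3.05 ± 0.80) and Bst1 (2.82 ± 0.62), and the Fgf13 call was lost without any 1 of the 3 arrays (adjusted p up to 0.0791). Of 13 Notch target genes 3 rose and 1 fell in LMO1 tumours, with Heyl at 1.59 ± 0.41 (adjusted p = 0.00795; 0.952 with an estimated correlation; 0.0523 within the 38-array set). LMO1 with Olig tumours had high Morc1 (2.30 ± 0.46) and Rpgrip1 (1.72 ± 0.42; adjusted p up to 0.0801 without replicate 1 or 2) and low Erdr1 (-2.28 ± 0.46). NUP98-HOXD13 tumours had high Pbx3, the gene of a HOX cofactor (1.59 ± 0.20), which rose with Hoxa7 (0.78 ± 0.20) among 6 HOX and cofactor genes (adjusted p = 0.0157; 0.952 with an estimated correlation). Gdpd3 rose there by 2.35 ± 0.42 and the class II chaperone gene Cd74 fell by 2.19 ± 0.38. Gdpd3 was also high in Rag with E2A knockout (2.47), E2A knockout (2.035) and Tal1 tumours (1.96). It was low in LMO1 (-1.70), LMO1 with Olig (-1.80) and Pokemon tumours (-1.85). Pokemon tumours had high Dsp (2.99 ± 0.69) and Bst1 (2.92 ± 0.76) and low Erdr1 (-3.03 ± 0.55).

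E2A knockout and Tal1 with LMO2 tumours had low transcripts of macrophages and matrix. The complement genes C1qa, C1qb and C1qc fell in E2A knockout tumours (-2.11, -2.63 and -2.67, n = 2) and in Tal1 with LMO2 tumours (-1.98, -2.16 and -2.25, n = 3). Of 18 myeloid genes 7 fell in the first (adjusted p = 4.29e-10; 0.127 with an estimated correlation) and 8 in the second (adjusted p = 4.97e-09; 0.177 with an estimated correlation). The collagen gene Col3a1 fell in both (-2.94 ± 0.53 and -3.09 ± 0.44), with 3 and 8 of 13 stromal, endothelial and epithelial genes (adjusted p = 2.59e-07 and 2.03e-08; 0.0669 and 0.0559 with an estimated correlation). The bacterial control bioB read 11.29 ± 0.40 and 10.99 ± 0.22 on these arrays, and was as high in Tal1 (11.53 ± 0.05) and Rag with E2A knockout tumours (11.06 ± 0.33); over all 13 backgrounds other than the TLX1 groups, these included, it was 9.55 ± 1.11 (n = 41). H2-T3 was higher by 3.28 ± 0.76 in E2A knockout, 3.40 ± 0.76 in Rag with E2A knockout and 3.14 ± 0.63 in Tal1 with LMO2 tumours, or 2.85, 2.97 and 2.74 within the 38-array set, where the first and last did not pass (adjusted p = 0.0707 and 0.112). Tal1 tumours had high Ifi204 (2.80 ± 0.70) and low Cytip (-2.99 ± 0.60).

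P53 knockout tumours had high Prss22 (3.18 ± 0.31), Aqp8 (2.72 ± 0.22) and Mat1a (2.66 ± 0.23) and low Ripor2 (-2.13 ± 0.39) and Sh2d1a (-2.09 ± 0.34). For replicate 3, which lies in the 38-array set, these were 1.80, 1.71, 1.86, -1.90 and -1.56. Of 22 DNA replication genes 16 fell, among them Pola1 (-1.18 ± 0.25) and Rrm2 (-1.20 ± 0.25) (adjusted p = 0.00158; 0.952 with an estimated correlation; 0.97 for replicate 3 within the 38-array set). Replicate 2 was low in this list (median -1.36 against the other p53 knockout arrays) and in T-cell transcripts, with Cd3d at 8.50 against 12.62 and 13.09, and without it 2368 genes were called in place of 4042.

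The number of genes called per background, from 9157, was 4422 for Cdkn2a knockout, 3299 for beta-catenin, 2947 for Ikaros plastic, 2467 for ThPOK, 1023 for LMO1, 877 for LMO1 with Olig, 412 for Tal1 with LMO2, 332 for Tal1, 255 for E2A knockout, 202 for Pokemon, 194 for NUP98-HOXD13 and 175 for Rag with E2A knockout. P53 knockout gave 4042, TLX1 4343 and crossed tumours 5822. The log2 array median was 9.04 in Cdkn2a knockout, 9.08 in beta-catenin, 9.06 in Ikaros plastic and 9.01 in ThPOK tumours. It was 8.96 in p53 knockout, 8.99 in TLX1 and 8.61 in crossed tumours. In the backgrounds with 1023 calls or fewer it lay between 8.80 (LMO1) and 8.90 (Tal1). Large counts thus went with array medians outside that range, and whether array scaling moved the counts was not tested. Leaving out any 1 array of the background moved the count by over 1.5 times for LMO1 (195 to 423), LMO1 with Olig (277 to 452), Tal1 with LMO2 (115 to 197), Tal1 (59 to 106), E2A knockout (17 to 94), Pokemon (9 to 53), NUP98-HOXD13 (50 to 116), Rag with E2A knockout (4 to 43) and ThPOK (1382 to 1581). So did leaving out Ikaros plastic replicate 2 (1065), beta-catenin replicate 3 (2183) and p53 knockout replicate 2 (2368). In the 38-array set alone, LMO1 gave 2224, LMO1 with Olig 1693, Tal1 with LMO2 gave 219, and p53 knockout replicate 3, a lone array assumed to vary like the other groups, gave 1309. Most named genes of the backgrounds with 2 arrays lost their calls when either array was left out. Over 315 pairs of list and background 40 passed camera, 28 of them also within the 38-array set, and camera with an estimated correlation called 0 of the 315.

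**Figure D5:**
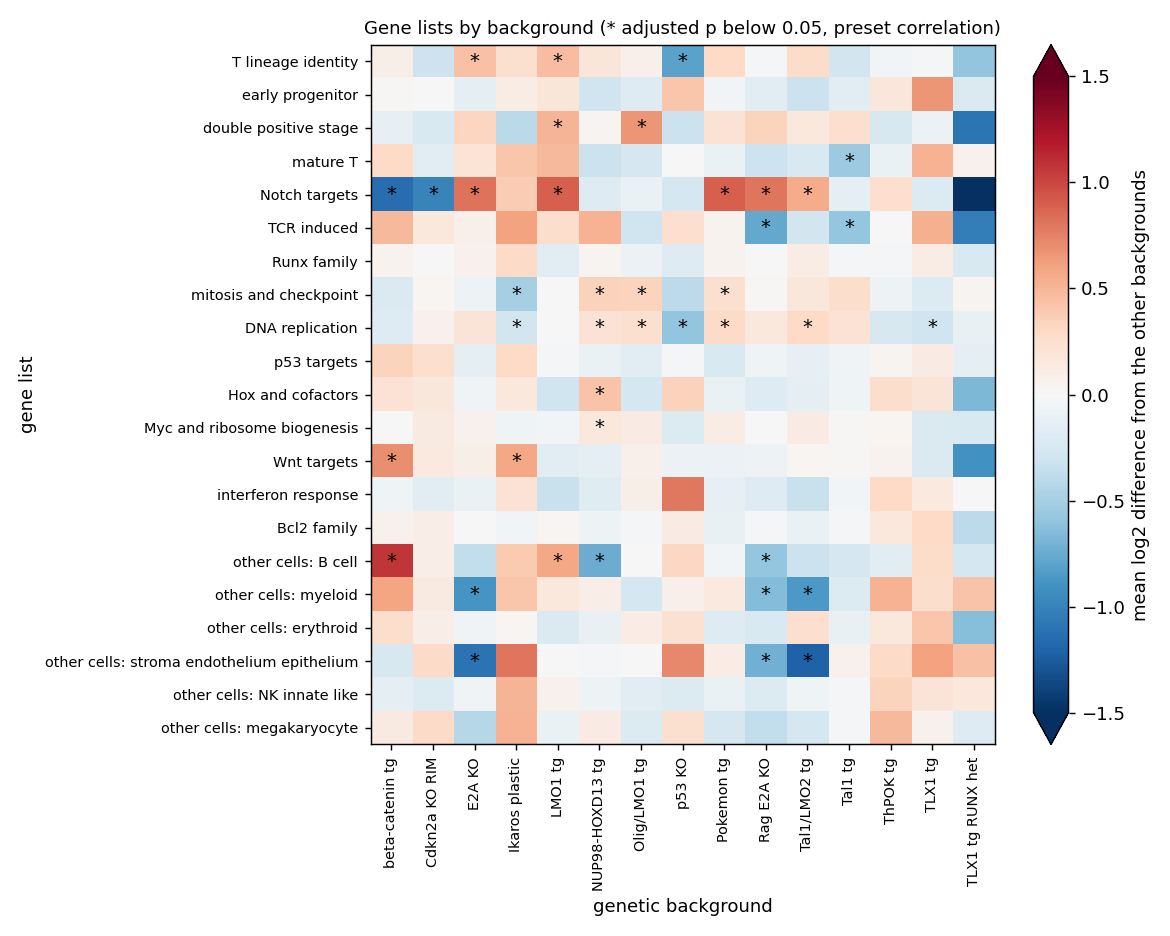
Mean log2 difference of each gene list (rows) in each background (columns) from the mean of the other backgrounds, with the colour scale ending at ±1.5 and a star for an adjusted p under 0.05. The Notch target list was low in beta-catenin (mean -1.15) and Cdkn2a knockout tumours (mean -0.999), and the Wnt target list was high in beta-catenin tumours (mean 0.70).

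Arrays of a background resembled each other more on average than arrays of different backgrounds, with exceptions. The mean Pearson correlation between arrays across 9157 genes was 0.924 within backgrounds (94 pairs) and 0.839 between them (1284 pairs), a difference of 0.085 (one-sided permutation p = 1e-05, the smallest that 100000 reassignments can give). Within the 38-array set the difference was 0.0512 with the same p. E2A knockout and Tal1 with LMO2 tumours correlated at 0.949, as E2A knockout tumours did with each other (0.949), LMO1 and LMO1 with Olig tumours at 0.937, and beta-catenin and Cdkn2a knockout tumours at 0.904. P53 knockout tumours correlated at 0.784 among themselves and at 0.836 with TLX1 tumours.

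Titles of the 9 Cdkn2a knockout tumours name genes or, as ras, a family, for which Nras was used here, and their levels were compared with the rest. Myb, a transcription factor gene, was 13.09 ± 0.13 (SD, n = 2) where the title names it and 12.49 ± 0.39 (n = 7) elsewhere, higher in 2 of 2 than in any of the 7 (two-sided exact permutation p = 0.0833, adjusted 0.125 over 3 tests). Myc was 12.31 ± 0.21 (n = 5) against 11.95 ± 0.21 (n = 4; exact permutation p = 0.0476, adjusted 0.125). Nras was 10.29 ± 0.18 where the title names ras (n = 3) against 10.23 ± 0.23 (n = 6; exact permutation p = 0.75, adjusted 0.75). None of these passed the correction. In the tumour whose title names Pim1 and Ccnd3, replicate 8, which also stood apart from the other 8 in Rag1 (8.14 against 11.53 ± 0.53) and in its log2 array median (9.20 against 9.02 ± 0.04), Pim1 was 9.01 and Ccnd3 11.05, and all 8 other tumours were above it for both genes (9.502 ± 0.40 and 11.86 ± 0.59).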

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

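The tests of array set, array processing, probe sets, cell type and RNA quality in this part were chosen after the results were seen, and the splits of the samples were fixed before.

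The difference between TLX1 tumours and the other backgrounds is the first pattern weighed, with 2936 genes called against 31 in the highest of 99 other splits, so a chance split of single arrays can be excluded for this count (1 of 100 splits, the real one); such splits mix backgrounds, whose arrays resemble each other, and with background as a random block 190 genes were higher and 17 lower. Among p53 knockout tumours, the arrays in the TLX1 array set minus the array outside it correlated with the TLX1 difference at r = 0.676 across the 3651 genes called when p53 knockout arrays were left out of the controls (0.689 with replicate 1 alone), which array set or RNA quality would give. As the whole cause these would leave no difference within the set, and there the median in the called direction was -0.0712 (-0.0343 with p53 knockout replicate 1 alone), with 0 genes called by limma (891 at an unadjusted p under 0.05) against up to 51 in 28 splits of the 8 arrays. Dlx1 (2.68) and Smim3 (1.73) kept their size within the set without passing the threshold there (limma, adjusted p = 0.0508 and 0.396). They passed it with array set as a block (limma, adjusted p = 0.0429 and 0.0225), which leaves these differences as they are and changes only the spread. With p53 knockout replicate 2 also left out the differences were 2.54 and 1.63 and the calls were lost. That fit has a lone control array in the set, so the loss cannot show whether the calls rest on replicate 2. A difference with the transgene stays open, not shown. Array set and RNA quality could therefore account for most of the called genes. The only controls in this set are p53 knockout tumours, so the comparison cannot tell this from levels that TLX1 and p53 knockout tumours share. P53 knockout replicate 3, outside the set and with a beta-actin ratio of 0.27, was also high in such genes. It read 9.59 for Dok5, 9.16 for Klf15 and 9.32 for Caln1. The means over the 41 tumours of other backgrounds were 7.85, 7.69 and 7.84. Of the 10 genes named as highest, only Dlx1 went the other way (7.29 against 7.74). Replicate 3 is not clear of array processing. Its bacterial controls lys and trpn (log2) read 8.56 and 7.32, between the means of TLX1 tumours (9.335 and 6.93) and of the 41 others (7.83 and 7.72). ThPOK replicate 2, with lys at 8.56 and trpn at 7.44, read 8.26 for Dok5. With 1 array and top genes alone, shared levels stay open. In simulation, 6 against 2 arrays recovered 43.3% of changes of log2 1, with the spread pooled within all 15 backgrounds. Arrays correlated at 0.784 in p53 knockout and 0.892 in TLX1 tumours, against 0.924 within backgrounds on average, so the real recovery may be lower.

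The difference between crossed and TLX1 tumours is the second, with 4959 genes called against 2291 in the highest other split (1 of 100 splits as large, the real one), so chance can be excluded for the count. Of the bacterial control probe sets, a share of 0.778 was called between the groups, beside 0.542 of the genes; the array sets were found from these same probe sets, so this restates that split and is no separate test, and different array processing may account for part of the difference. Other probe sets of the 2-fold genes had a median of 0.67 where the probe set used had 1.46, a ratio of 0.458 (0.322 for the higher genes, with 14 of 37 of opposite sign, and 0.431 for the lower genes, with 42 of 215), which leaves open, most of all for the higher genes, that single probe sets rather than genes carry the signal. The groups lie in different array sets, so array processing and RUNX heterozygosity cannot be told apart. Rag2 (-3.36), Dtx1 (-3.38) and Ptcra (-2.73) are open to both.

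The third is p53 knockout replicate 2, whose T-lineage genes had a median of -1.91 against the mean of the other p53 knockout arrays, with Cd3g at 7.85 against 11.75 and 12.94. The endothelial genes Pecam1, Cdh5 and Vwf had a median of 2.44 there, with Cdh5 at 12.74 against 8.26 and 8.74, Pecam1 at 11.98 against 9.69 and 9.41, and Vwf at 8.33 against 8.02 and 7.77. The abundant T-cell transcripts Thy1 and Ptprc read 11.59 and 11.14, below the 12.21 and 12.37 of the lowest of the 50 arrays outside the p53 knockout background. A candidate explanation is cells of another type, endothelial among them, in place of part of the T cells, with medians of 1.10 for the list of stroma, endothelium and epithelium and 1.25 for B-cell genes. Its beta-actin ratio of 1.09 lay within the 0.79 to 2.17 of the other 7 arrays of its set, which argues against low RNA quality of this array alone.

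For crossed tumours against the other backgrounds, 5114 genes were called against 126 in the highest other split (1 of 100), so a chance split of single arrays can be excluded; these splits mix backgrounds too, and with background as a random block 241 genes were higher and 1840 lower. For the gene lists it cannot be excluded: camera called 3 lists in TLX1 tumours where 59 of 100 splits called as many (highest other 9), 1 between the TLX1 groups (81 of 100; highest other 10) and 0 in crossed tumours against the other backgrounds (100 of 100; highest other 10).

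In opposite directions against the other backgrounds, and between the TLX1 groups as well, 993 genes were called. Of these, 852 were higher in TLX1 and lower in crossed tumours (643 if the lists were independent) and 141 the reverse (225), but the shared controls make independence no fair expectation. By the difference of crossed from TLX1 tumours these include Prss22 (-5.77), Kalrn (-5.29), Lig3 (-4.82), Krtap19-1 (-4.73), Slco6c1 (-4.64), Samhd1 (-4.46), Steap1 (-4.38), Tspan33 (-4.25), Mat1a (-4.24), Nr4a3 (-4.23), Caln1 (-4.22), Dok5 (-4.15), Fmo2 (-4.08), Serpinf1 (-3.89), Rag2 (-3.36), Hoxa13 (-3.35), Hba-a1 (-3.11), Flt3 (-2.84), Kit (-2.09) and Sp3 (2.56). The 18S control probe set, outside the gene comparisons, read 12.71 in crossed tumours against 8.84 in the other backgrounds.

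Single samples far from their group were seen in 21 of 201 groups of values checked, where chance gives about 1 in 20. Crossed replicate 5 was high in Cd8a (10.70 against 8.68 ± 0.17, SD of the other 5), Cd8b1 (10.83 against 8.28 ± 0.35), Rag1 (10.68 against 8.14 ± 0.44) and Cd79a (7.83 against 7.402 ± 0.06). Crossed replicate 1 was high in Itgam (10.38 against 8.27 ± 0.18), Lmo2 (11.71 against 9.18 ± 0.24), Samhd1 (7.83 against 7.15 ± 0.08) and the Gapdh 3' to 5' ratio (0.40 against 0.06 ± 0.04), and low in Il7r (8.99 against 11.87 ± 0.50) and Emid1 (9.65 against 11.99 ± 0.26). Crossed replicate 2 was low in Smim3 (8.004 against 10.64 ± 0.34) and replicate 3 high in Usp25 (11.29 against 10.87 ± 0.04). TLX1 replicate 1 was low in Cd8a (9.67 against 11.33 ± 0.15) and high in Gsdme (9.14 against 7.91 ± 0.21), and TLX1 replicate 5 was high in Cd79a (10.05 against 8.94 ± 0.18). Cdkn2a knockout replicate 8 was low in Rag1 (8.14 against 11.53 ± 0.53) and Tcf3 (10.19 against 10.72 ± 0.10) and high in Zbtb7b (9.89 against 9.31 ± 0.09) and in its log2 array median (9.20 against 9.02 ± 0.04). Cdkn2a knockout replicate 6 was high in the beta-actin ratio (0.43 against 0.13 ± 0.04) and the Gapdh ratio (0.24 against -0.05 ± 0.04).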

How the results depend on the processing

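Array set, the p53 knockout arrays as only controls, the beta-actin covariate, arrays left out for their ratio and the largest array set alone were chosen after seeing the data. Of 362 alternative values of the main counts and tests, 281 stayed (counts within 1.5 times) and 81 moved; of the values of single genes and lists, 3445 stayed, 254 lost and 7 gained a call and 80 turned direction. Unless the construction shows it (fewer or more genes or samples), the cause was not tested. Signal over background limits low genes, which the filters test.

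TLX1 against other backgrounds gave 2890 genes higher with no filter, 947 higher and 735 lower with the stricter filter, 2299 lower with both TLX1 groups together, 1834 lower with 1 mean per background, 190 and 17 with background as a random block, 0 and 0 in limma against p53 knockout arrays 1 and 2 (891 unadjusted), 58 and 78 with array set as a block (2 and 3 without p53 knockout array 2), 81 and 22 with the beta-actin covariate and 1108 and 656 without the 2 arrays of highest ratio. Without single replicates it gave 1290 to 1667 and 897 to 1152. Crossed against TLX1 tumours gave 5454 lower with no filter, 1608 lower with the stricter filter and 3860 and 2050 with arrays centred (leave-one-out 1460 to 1709 and 3151 to 3334). Crossed against other backgrounds gave 5276 lower with no filter, 1637 lower with the stricter filter, 3623 and 2146 centred and 241 and 1840 with background as a random block (leave-one-out 1500 to 1551 and 3222 to 3268).

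With a replicate block, TLX1 tumours against the other backgrounds gave 922 and 403, and crossed tumours against them 1130 higher. The numbers do not pair the samples: 1 of 6 pairs had a correlation of deviations above 0.1, so the replicate block is no paired test.

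The correlation of the TLX1 groups was 0.0889 and -0.229 with controls split and 0.0149 with the mean of probe sets. With an estimated correlation camera called 0 lists in TLX1 tumours, 0 between the TLX1 groups and 0 by background, with the mean of probe sets 0 between the TLX1 groups, and fry called 6, 14 and 11 in the order of the comparisons above. With no filter LMO1 gave 2262, NUP98-HOXD13 335, LMO1 with Olig 1976, Pokemon 330, Tal1 521 and beta-catenin 4962. In the largest array set E2A knockout gave 439, LMO1 2224, NUP98-HOXD13 449, LMO1 with Olig 1693, Pokemon 459, Rag with E2A knockout 692, Tal1 with LMO2 219, Tal1 557 and p53 knockout 1309. Without single replicates the ranges were 4109 to 4356 for Cdkn2a knockout, 17 to 94 for E2A knockout, 1065 to 2775 for Ikaros plastic, 195 to 423 for LMO1, 50 to 116 for NUP98-HOXD13, 277 to 452 for LMO1 with Olig, 9 to 53 for Pokemon, 4 to 43 for Rag with E2A knockout, 3737 to 4257 for TLX1, 5548 to 5635 for crossed, 115 to 197 for Tal1 with LMO2, 59 to 106 for Tal1, 1382 to 1581 for ThPOK, 2183 to 2430 for beta-catenin, 2368 to 4481 for p53 knockout tumours and 10 to 11 for targeted genes.

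Array set as a block gives the same TLX1 difference as p53 knockout arrays 1 and 2 alone, so it is no second check of direction. Under both settings these TLX1 differences turned direction: Dok5 -0.027, Prss22 -0.92, Caln1 -0.47, Serpinf1 -0.62, Mat1a -0.59, Dll4 -0.25, Fmo2 -0.41, H2-T3 0.10, Cldn10 0.37, Ctse 1.32, Sp3 0.33, Sephs2 0.14, Moxd2 0.46, Flt3 -0.52, Kit -0.77, Rfc3 0.33, Eif4a1 0.25, Myc 0.25, Lef1 0.87, Cd8b1 0.69, Csf1r -0.52, Hba-a1 -0.92 and Runx1 0.07. With the block and without array 2 these did: Dok5 -0.12, Prss22 -0.61, Caln1 -0.55, Serpinf1 -0.55, Mat1a -0.45, Fmo2 -0.45, Cldn10 0.39, Smim10l1 0.19, Ctse 0.56, Moxd2 0.57, Flt3 -0.49, Kit -0.71, Eif4a1 0.075, Myc 0.39, Lef1 0.33, Csf1r -0.10, Hba-a1 -0.84 and Runx1 0.066. With both TLX1 groups Prss22 was -0.23, Bcl11a -0.083 and Hba-a1 -0.39. With the covariate Ctse was 0.51, Runx1 0.22 and, between the TLX1 groups, Dlx1 -0.14. With the probe set of largest range, crossed minus TLX1 was -0.053 for Fli1, 0.72 for Samhd1, 1.74 for Kit and 0.48 for Runx1. Against p53 knockout arrays 1 and 2 the early progenitor, DNA replication and Myc lists turned (adjusted p = 0.834, 4.85e-05 and 0.61), with replicate 2 itself low in DNA replication genes (-1.36). Hoxd13 was 0.001 and Tlx1 in TLX1 tumours -0.069 with quantile normalization, and Cdkn2a lay between -0.034 and 0.015 without single replicates, above 0 without replicate 6. Hoxd13, Tlx1 and Cdkn2a passed no threshold there.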

Other observations

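The values in the next 2 paragraphs were chosen after they were seen, and the splits of the samples were fixed before.

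Dlx1, high in both TLX1 groups, was also high on single arrays of other backgrounds. It read 8.47, 10.08 and 10.20 in NUP98-HOXD13 tumours, 10.28, 9.10 and 8.997 in LMO1 with Olig tumours, 9.60 and 7.22 in Tal1 tumours and 8.01 and 9.33 in Rag with E2A knockout tumours, beside 7.09 to 7.41 in LMO1 tumours. Smim3 read 7.91, 9.22 and 10.17 in the same NUP98-HOXD13 tumours. Ikzf1, the Ikaros gene, lay between 8.07 and 8.53 on the 6 crossed arrays and averaged 10.25 ± 0.59 (SD, n = 6) in TLX1 tumours.

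Single arrays differed from others of their background in Dtx1, Ptcra or Rag1. TLX1 replicates 1 and 6 had Dtx1 at 9.12 and 9.02, Rag1 at 9.25 and 9.502 and Notch3 at 8.89 and 9.13, while replicates 2 to 5 had Dtx1 at 11.38 or more, Rag1 at 11.31 or more and Notch3 at 10.82 or more, within a single array set. Cdkn2a knockout replicate 7 had Dtx1 at 12.23 and Ptcra at 10.45, where the other 8 tumours of that background lay between 8.53 and 9.18 and between 7.85 and 8.51; its Notch3 (8.86) lay among theirs and its Rag2 (8.40) below theirs. NUP98-HOXD13 replicate 3 had Rag1 at 8.88, Ptcra at 7.98 and Dtx1 at 8.34, against 11.92 and 11.83, 10.82 and 10.02, and 11.83 and 12.29 in the other tumours of that background. None of these was tested.

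Reassigning the background labels 100 times, the real labels included, excluded chance for the number of genes called in most backgrounds of 3 or more arrays. The backgrounds of 2 arrays (E2A knockout, Rag with E2A knockout, Pokemon and Tal1) were not assessed in this way. The real labels gave the highest count (1 of 100) for TLX1 (4343 genes; highest other 172), crossed (5822; 561), Cdkn2a knockout (4422; 2), beta-catenin (3299; 3049), Ikaros plastic (2947; 1259), LMO1 (1023; 19), ThPOK (2467; 1889) and p53 knockout tumours (4042; 1913). It was 2 of 100 for NUP98-HOXD13 (194; 1075) and 3 of 100 for LMO1 with Olig tumours (877; 1217). For Tal1 with LMO2 tumours 5 of 100 gave as many (412; 2721), so chance cannot be excluded there. Reassignments that call several times the real count, as for NUP98-HOXD13 and Tal1 with LMO2, may point to a structure of the samples; which arrays they grouped was not examined. For targeted genes chance can be excluded (11 pairs, 2 of them lower where the label names a transgene; highest other 3; 1 of 100), and for the lists by background it cannot (40 pairs; highest other 73; 69 of 100).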
